A study of Arabidopsis thaliana with 4 samples.

How the data were processed

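Chromatin immunoprecipitation on a tiling array (ChIP-chip) was used to measure acetylation of lysine 56 of histone H3 (H3K56ac) in Arabidopsis thaliana seedlings of the Col-0 accession. Per the labels' protocols, seedlings were grown in liquid medium at 22 °C with a photoperiod of 16 hours and labelled as 10 days old. Immunoprecipitated (IP) DNA and input DNA, the chromatin before immunoprecipitation, were amplified, labelled with Cy3 and Cy5 and hybridised to the same array, per the labels. Preparations I and II are called replicates 1 and 2 here. Each was hybridised to 2 arrays, once with the IP in Cy5 and once with the IP in Cy3, which makes 4 arrays.

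The table analysed was the authors' deposited processed values, with 1 column per array and 21800 rows. The deposited values are log ratios of the 2 channels. Their log base, their direction (IP over input or the reverse), the normalization and the software are not given in the sources used here. The arrays of a dye-swap pair held identical values at all 21707 measured tiles in both replicates. Each column was therefore taken as the value of a pair and not of an array. How that value was made is not given, so whether a dye effect cancels in it is not known. The dye effect, each array's own ratio and the spread between dye-swapped arrays can therefore not be computed from this table. The column medians as deposited were −0.737 in replicate 1 and −0.925 in replicate 2, so the values had not been centred on 0. A difference of 1 in these values is called 1 log unit. It would be a 2-fold difference if the base were 2.

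No direction was assigned to the ratio, since the labels give the dye of each channel but not which channel was the numerator. The tests were planned as tiles higher or lower in the IP than in input, and they are reported as tiles above or below the median of the deposited ratio. The correlation of the replicates was positive, so both ran the same way. No gene name or position was given with the tile IDs in the files used here, and the gene table at hand lists loci and not tiles, so no tile was assigned to a gene, an exon or a coordinate. For the same reason the planned tests of 8 gene lists (housekeeping, photosynthesis, ribosomal protein, developmental regulator, seed storage, RPP4 and RPP5 cluster, CBF and histone genes) and of annotation classes were not run.

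The columns of each replicate were averaged, which left 2 values per tile, and the median over tiles was taken off each replicate. The 93 rows with no value in any column were left out. They were 54 tiles and 39 entries with other IDs. Each tile's mean was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept and eBayes, two-sided, 1 residual degree of freedom per tile), with Benjamini-Hochberg adjustment over all 21707 tiles and a threshold of 0.05. A zero in this test is the array median and not a level without H3K56ac. The labels do not say whether preparations I and II came from separate cultures, so p-values cover no more than these 2 preparations. They rest on the spread between the 2 pooled over all tiles, which are not independent. The number of arrays limits the precision. The prior SD of a tile was 0.184 log units with 134 prior degrees of freedom, the median standard error of a mean was 0.130, and the smallest absolute mean that passed was 0.281. With 134 prior degrees of freedom against 1 residual, a tile's own spread hardly entered its standard error. A call was thus close to a fixed cutoff on the absolute mean. TA01A10, at 0.113 in replicate 1 and −1.41 in replicate 2, passed with a standard error of 0.145 (limma adjusted p = 4.55e-05). The fit was tested on simulated data with the same 21707 tiles, of which 200 were shifted. It recovered 59% of 100 tiles shifted by 0.5 and 100% of 100 tiles shifted by 1, with 3 false calls. The simulated tiles were independent, with variances drawn from the fitted prior. In the data 64.2% of tiles were called, and the replicate differences of neighbouring tiles correlated at 0.297. The shares recovered and the false calls therefore describe the simulation and not the calls made here.

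Tiles were named by a rule set before the data were examined, namely the 2 highest and 2 lowest called tiles with the same sign in both replicates. Tile IDs consist of a series (TA, TB, TC, TD or PD), a plate number, a row letter and a column number. Tiles were ordered by plate, row and column within a series, with 96 wells on a plate and 12 in a row. Correlations of tiles at a given distance in that order were computed across pairs of tiles with Python 3.11.15 and numpy 2.4.6. The 95% intervals of these correlations treat pairs as independent and are too narrow. Called tiles were also shuffled within plates 1000 times, and plate medians were shuffled 100000 times. These steps, and a definition of low blocks as 3 or more plates in a row with a median of −0.4 or less, were chosen after the data were seen.

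The alternatives fixed before the data were examined were values as deposited, centring on the mode, scaling to a common median absolute deviation, robust eBayes, a test against a log2 of 1.5 (treat), a 2-component Gaussian mixture (scikit-learn 1.9.0) and leaving out each replicate.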

Results

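H3K56ac, a mark on the lateral surface of the nucleosome core that is associated with actively transcribed chromatin and with newly deposited histone H3, was profiled in 10-day-old Arabidopsis seedlings without treatment. The design holds 1 comparison, IP DNA against input DNA on the same array. It was made in 2 chromatin preparations with a dye swap each. Of the 21761 tiles on the array, 21707 had a value, and every one of these was measured in both replicates. Both arrays of a dye-swap pair carried identical values and were counted as 1 sample, so n = 2 throughout. As deposited, 17.8% of the tiles in replicate 1 and 11.6% in replicate 2 had a log ratio above 0.

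The first question was how far the 2 preparations gave the same profile. Across the 21707 tiles the centred log ratios of replicates 1 and 2 had a Pearson r of 0.920 and a Spearman rho of 0.903. These are correlations across tiles, which are not independent replicates. The difference between replicates had an SD of 0.269 log units, against an SD of 0.657 for the mean of both over tiles. The slope of replicate 2 on replicate 1 was 0.903. The replicates lay on opposite sides of the median at 3109 tiles (14.3%). The correlation was 0.919 within the TA tiles, 0.900 within TB, 0.939 within TC, 0.858 within the 316 PD tiles and 0.905 within the 96 TD tiles. Within the low blocks described further on, a subset chosen after seeing the data, Pearson r was 0.840 and Spearman rho 0.739. Among all other tiles they were 0.907 and 0.879. The SD of the difference was close in both (0.274 and 0.268).

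**Figure D1:**
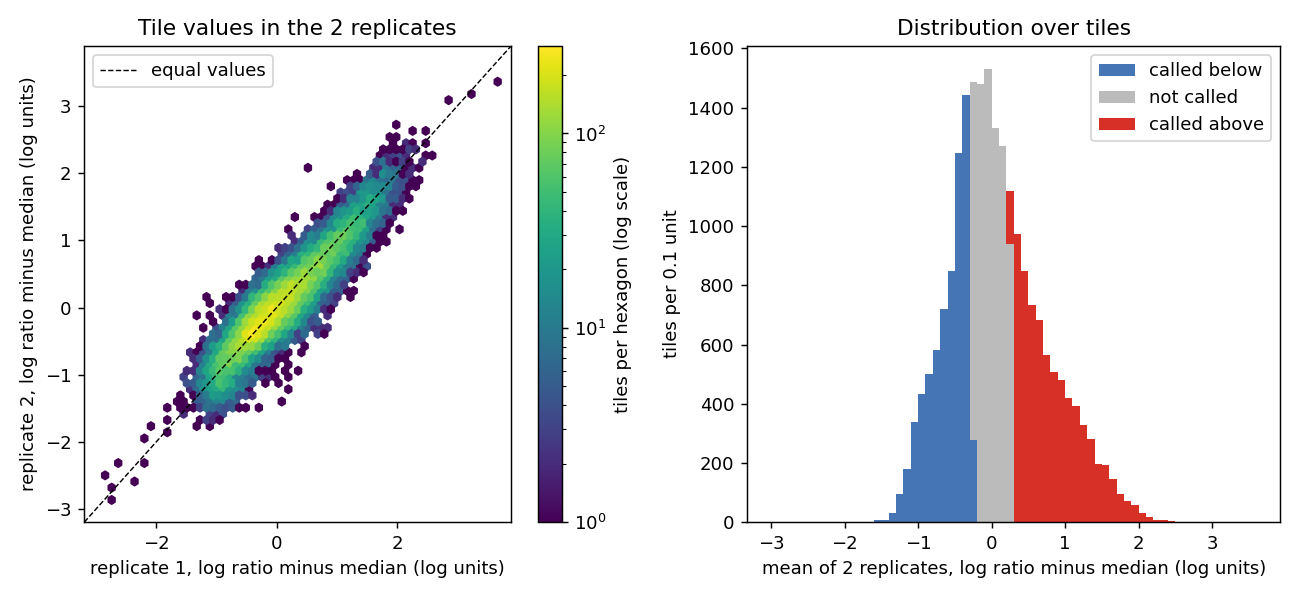
Left, the centred log ratio of every tile in replicate 1 (x) against replicate 2 (y), in log units, with the colour giving tiles per hexagon on a log scale and the dashed line equal values. Right, the number of tiles per 0.1 log unit of the mean of 2 replicates, split into tiles called below the median, not called and called above it by limma; 2257 tiles lay 1 unit or more above the median and 667 lay as far below.

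The log ratio of the 2 channels, IP and input with the numerator not stated, varied widely between tiles. At most of them the mean lay far from the median against a spread pooled over tiles. By limma at an adjusted p of 0.05, 7227 tiles (33.3%) lay above the array median and 6716 tiles (30.9%) lay below it, while 7764 tiles (35.8%) did not pass. Among the called tiles, 45 had opposite signs in the 2 replicates. The share of calls above the median was thus 51.8%. That split depended on the size of change asked for and on where 0 was put. A test against a log2 of 1.5 (treat), which is 0.585 log units, called 2756 tiles above and 1110 below. That is a 1.5-fold change only if the base of the deposited ratios is 2. A 2-component Gaussian mixture placed 1621 tiles in its upper component and 8274 in its lower one at a posterior over 0.95, and left the others unassigned. Its lower component had a mean of −0.186 and a weight of 73.6%, so it was the bulk of tiles around the median. These 2 counts are therefore not a split at the median. With the ratios as deposited, whose median was lower by 0.83 log units, 1534 tiles were above 0 and 16371 below (8.57% above). With each replicate centred on its mode, which raised the median by 0.27, 10366 were above and 3167 below (76.6% above). The ranking of tiles does not change with centring, but no count here states how many tiles carried the mark.

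Around the median the profile was asymmetric. At a distance of 1 log unit or more from it there were 2257 tiles above and 667 below, and 1858 and 321 of these, respectively, reached that distance in both replicates. These counts too depended on the zero point, and their order turned with the ratios as deposited (181 tiles at 1 or more and 8397 at −1 or less), while centring on the mode gave 3626 and 73. At 1.5 units from the median the numbers were 636 above and 17 below. The count below rested on few tiles and was 20 in replicate 1 alone and 37 in replicate 2 alone. At 2 units there were 72 above and 7 below. The 95th percentile of the mean lay at 1.31 and the 5th at −0.902, and the skewness over tiles, which does not depend on centring, was 0.51.

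The tile with the highest ratio was TB15F09, at 3.52 ± 0.219 log units above the median (mean ± SD, n = 2; limma adjusted p = 4.23e-52). Its neighbours in ID order lay at 1.24 and 2.41. The second was TB16A09, at 3.20 ± 0.0838 (limma adjusted p = 5.88e-48), whose neighbours lay at 1.93 and 0.37. At the other end, TA06C04 lay at −2.81 ± 0.0873 (limma adjusted p = 4.63e-42), next to a tile at −2.48 on one side and one at −1.19 on the other. TA58A11 lay at −2.70 ± 0.0622 (limma adjusted p = 1.66e-40), between a tile at −2.28 and one at 1.62. After TA58A11 the value thus rose above the median from one tile to the next. The p-values of these 4 tiles rest mostly on the variance pooled over tiles and little on the 2 values of each.

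The series of tiles differed in level. The TB tiles had a median of 0.18 ± 0.0282 log units (mean and SD of the replicate medians, n = 2), with 42.8% of 9577 tiles called above and 16.7% called below. The TA tiles had a median of −0.16 ± 0.0224, with 25.3% of 9304 called above and 40.8% below. The TC tiles had a median of −0.31 ± 0.0200, with 25.9% of 2414 called above and 51.1% below. The TC series held plates of high and of low level. Without the plates of the low blocks described further on, a comparison chosen after seeing the data, the 1344 remaining TC tiles had a median of 0.22 ± 0.0303, with 45.4% called above, and the 7240 remaining TA tiles one of −0.02 ± 0.0106. The PD tiles stood at 0.13 ± 0.0436 and the TD tiles at −0.13 ± 0.158. Over all tiles the differences between TA, TB and TC were larger than the SD between replicates. All series were measured in the same 2 preparations, so these comparisons are paired. The medians of TA, TB and TC were −0.176, 0.202 and −0.321 in replicate 1 and −0.145, 0.162 and −0.293 in replicate 2, in the same order. With 2 pairs no permutation over preparations can reach 0.05, and none was run.

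Log ratios were similar at tiles with neighbouring IDs. The correlation of the mean log ratio between neighbours was 0.621 over 21567 pairs, fell to 0.429 for tiles 2 wells apart and to 0.291 at 10 wells, and was −0.00193 between neighbours after the tiles were shuffled. When replicate 1 at a tile was set against replicate 2 at its neighbour, so that no preparation entered on both sides, it was 0.584. The slow fall over all tiles came with differences in level between plates. After plate medians were taken off, the correlation of all tiles was 0.482 between neighbours, 0.219 at 2 wells and 0.0938 at 5 wells, close to that of the TB tiles as measured (0.468, 0.204 and 0.0989). Outside the low blocks described below, a subset chosen after seeing the data, it was 0.511, 0.263 and 0.157. Tiles called above the median formed 2651 runs of consecutive IDs with a mean length of 2.73 tiles, against 1.70 after shuffling within plates (highest of 1000 shuffles 1.73). Tiles called below formed 2107 runs with a mean length of 3.19 tiles against 2.04 (highest 2.10). Both permutation tests (one-sided) gave p = 0.001, the smallest that 1000 shuffles can give, and 0.001 after Benjamini-Hochberg adjustment over 6 such tests. A single tile made up 34.4% of the runs above and 55.0% of the runs below.

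**Figure D2:**
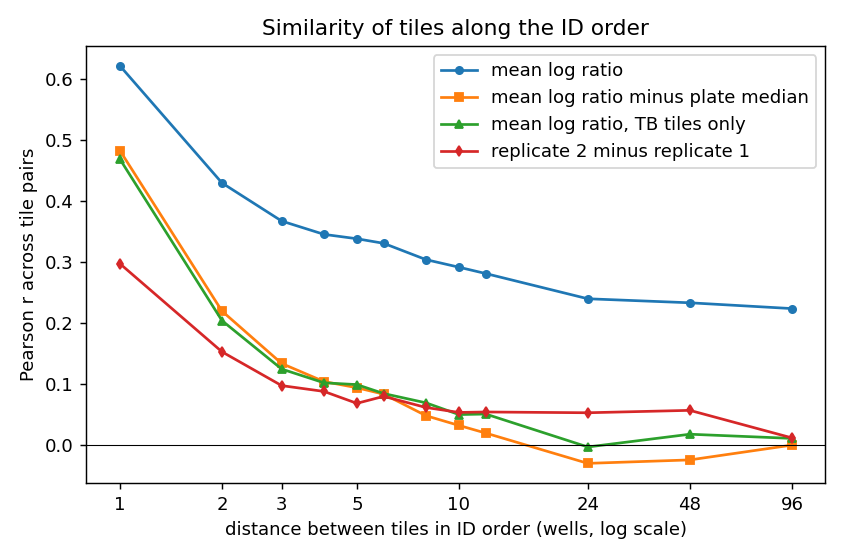
Pearson r across pairs of tiles (y) against their distance in ID order, in wells on a log scale (x), for the mean log ratio, the same after plate medians were taken off, the mean log ratio of TB tiles, and the difference between replicates. The first starts at 0.621 and is still at 0.224 at a distance of 96 wells; after plate medians were taken off the correlation starts at 0.482 and is near 0 at that distance.

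Long stretches of plates next to each other in ID order had low ratios. Plates 21 to 28 of the TA series (713 tiles) had a median of −0.58 ± 0.0687 log units (mean and SD of the replicate medians, n = 2), plates 37 to 51 of the same series (1351 tiles) one of −0.71 ± 0.0380, and plates 17 to 29 of the TC series (12 plates, 1070 tiles) one of −0.75 ± 0.0502. All other tiles had a median of 0.10 ± 0.0116. These 3 blocks held 14.4% of the tiles, 39.6% of those called below the median and 84.1% of those 1 log unit or more below it. Because the blocks were picked for their low medians, these shares describe them and are no test. They also depend on how a block was defined. Plates 57 and 58 of TA, with medians of −0.544 and −0.575, were counted among all other tiles because their run was too short. Both lay lower than plate 48 of TA (−0.447), which was inside a block. Plate 30 of TC, at −0.396, narrowly missed the cutoff. Within the blocks 138 tiles (4.40%) were called above the median and 38 lay 1 log unit or more above it, against 38.2% called above among all other tiles. The 3 blocks differed in this, with 76 of 713 tiles called above in the first (10.7%), 46 of 1351 in the second (3.40%) and 16 of 1070 in the third. Plate medians followed those of the plate before (r = 0.741 over 99 TA plates and 0.871 over 27 TC plates; one-sided permutation p = 1e-05 each, the smallest that 100000 shuffles can give, adjusted p = 1.5e-05). No tile with a value had a TC plate number between 13 and 17 or between 25 and 27. Across these gaps the next plate present was used, for the correlations and for the blocks. Over the first gap the TC median went from 0.41 in plate 13 to −0.43 in plate 17, and the 0.871 includes that step. In the 100 TB plates r was 0.159 (p = 0.0449 by the same permutation test, adjusted p = 0.0449), and no TB plate had a median below −0.158 in the mean of the replicates.

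**Figure D3:**
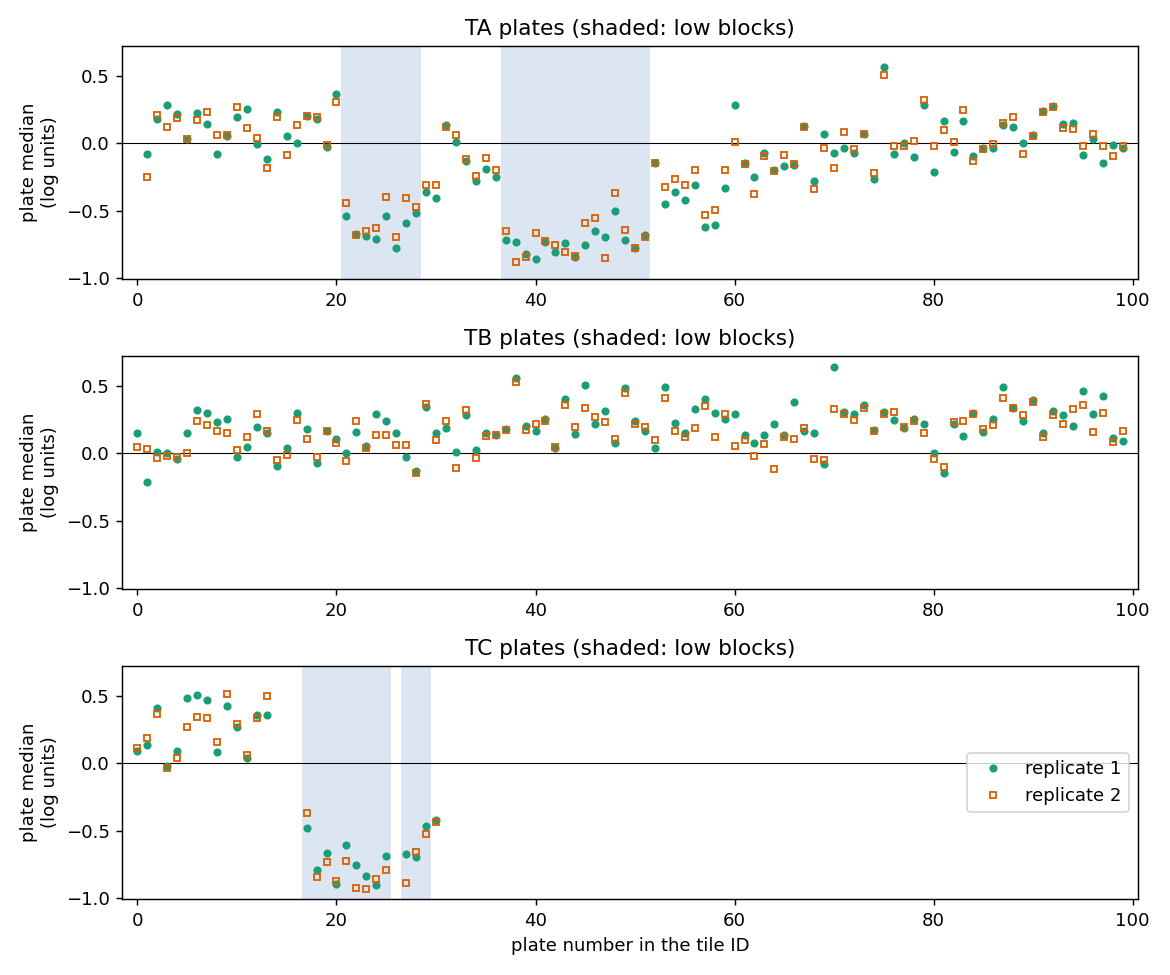
Median centred log ratio of each plate, in log units (y), against the plate number in the tile ID (x), for the TA, TB and TC series, with filled circles for replicate 1 and open squares for replicate 2; shading marks the low blocks. In both replicates the shaded plates lie below 0, and the TB plates range from −0.158 to 0.548 in the mean of the replicates.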

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

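The counts of tiles depended on the zero point and the size of change asked for. They changed little with scaling, and robust eBayes called 7236 tiles above and 6724 below. Robust eBayes also pools the variance over tiles, so how far the counts rest on the variance model was not tested. With values as deposited, 1534 tiles were above and 16371 below, with 181 and 8397 at 1 log unit or more. With centring on the mode, 10366 were above and 3167 below, with 3626 and 73 at 1 unit or more. Since each replicate is moved by 1 constant, the shift itself is the cause. A test against a log2 of 1.5 called 2756 above and 1110 below. At a posterior over 0.95 the Gaussian mixture placed 1621 tiles in its upper and 8274 in its lower component. The lower component is the bulk of tiles around the median, so these counts cannot be set against the main split (7227 and 6716). All 2756 and all 1621 were among the 7227, which is no support for the calls. The treat test is a stricter test of the same means, and the mixture set a higher cutoff on them. Of the recomputed values, 40 (the 8274 and the 4 named tiles included) were classed as unchanged and 11 as moved (limit 1.5 times for a count). Of these 40, 22 were the named tiles and the shares called in a thinned set of tiles. That left 18 unchanged against 11 moved. The 10366 tiles above with centring on the mode also counted as unchanged under this limit. The named tiles add little to the 40, since they were picked as the most extreme. TB15F09 was classed as unchanged at 2.69 with values as deposited, against 3.52 in the main analysis. With n = 2 each replicate always lies within 1 SD of the mean, so leaving out 1 replicate could not test the named tiles. Without 1 replicate the tiles at 1 unit or more ranged from 2168 to 2465 above and from 640 to 836 below, the neighbour correlation from 0.600 to 0.617 and the tiles in low blocks from 3040 to 3196. Those last 2 ranges and the following alternatives were chosen after seeing the data. Leaving out the low blocks lowered the neighbour correlation to 0.511, and a plate median of −0.3 put 3941 tiles in low blocks. With that cutoff the first TA block and the TC block each reached to plate 30. Plates 53 to 55 and 57 to 59 of TA became further blocks, and the block of plates 37 to 51 stayed the same. The shares of tiles held by the blocks were not recomputed for this cutoff. The limma counts without 1 replicate could not be made, since no residual degrees of freedom remain. The fit with a dye term and the fits to 1 dye orientation were not run because the swapped columns are identical, and a filter for tiles on all arrays removes none.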

Other observations

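The tests on plate medians, on well position, on row changes, on the 95th percentile of all low blocks together, on the 4 block edges together and on the level-dependent scale were set before their values were seen; those on single blocks, on the spread within plates, on single edges and on plate-wide shifts between replicates were chosen afterwards.

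The longest runs of extreme tiles lay in different plates. Tiles 1 log unit or more above the median formed 1589 runs with a mean length of 1.42 tiles, against 1.15 after shuffling within plates. The longest had 8 tiles, as many as the longest in 1000 shuffles, and lay in plate 3 of the TC series, with a median of 1.42 in replicate 1 and 1.36 in replicate 2. Tiles 1 log unit or more below the median formed 382 runs with a mean length of 1.75 tiles against 1.23, and the longest had 10 tiles, in plate 23 of the TA series, against up to 12 after shuffling. The longest run of called tiles above the median had 30 tiles and began in plate 37 of the TB series (up to 29 after shuffling), and the longest called below had 102 and began in plate 17 of the TC series (up to 182).

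Why neighbouring IDs had similar ratios can be narrowed down. A plate-wide amplification or printing effect would vanish once plate medians are taken off, but the correlation of neighbours was then still 0.482 (95% interval 0.472 to 0.493). An effect of the well's place on the plate is argued against by the 0.622 that remained after the mean of each well position was taken off. The correlation across a change of row was 0.620 (0.589 to 0.650), against 0.621 within rows, and 0.621 across a change of plate, as it would be if the order of the IDs followed the order of the tiles along DNA. That is a hypothesis from the data, since tile positions were not used here. What share of the similarity comes from DNA fragments that span adjacent tiles and what share from the extent of the mark was not tested.

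A constant shift of whole plates is argued against in 2 of the 3 low blocks. In all blocks together the 95th percentile was shifted by −1.13 against that of all other plates and the median by −0.806, and the difference of −0.325 met the bound set beforehand (more than 0.2 against a constant shift, 0.1 or less for it), although its 95% interval over resampled plates, −0.491 to −0.147, reached below 0.2. By block the difference was −0.454 (−0.606 to −0.174) in plates 37 to 51 of TA, where the whole interval lay beyond 0.1 but not beyond 0.2, −0.503 (−0.807 to −0.387) in plates 17 to 29 of TC, where it lay beyond both, and 0.085 (−0.238 to 0.358) in plates 21 to 28 of TA. A constant shift leaves the spread within a plate as it is. After plate medians were taken off, the 95th percentile still lay lower than in all other plates in TA 37 to 51 (difference −0.417, −0.589 to −0.295) and in TC 17 to 29 (−0.634, −0.781 to −0.405), with both intervals beyond 0.2. The interquartile range within plates was also smaller there, at 0.409 in TA 37 to 51 and 0.380 in TC 17 to 29 against 0.733. These tests address a shift by a constant only. A plate-wide change in the scale of the ratios was not tested. In TA 21 to 28 it differed by 0.158 (−0.207 to 0.497), so a constant shift stays open there. The planned test of the 4 edges of the TA blocks, which asked for at least 2 edges clearly over 12 wells from the change of plate, found 1 and was undecided. That edge, the start of the first block, lay 45 wells after the change of plate (13 to 52.8 with the interval widened for 4 edges), which argues against a change of plates as the place of that step; at the other 3 edges 0 intervals excluded the change of plate, so a change in plate production cannot be told apart from a change along the DNA there. Gene-poor heterochromatin is a candidate source of such blocks if the deposited ratio is IP over input, and it stays untested without tile positions and a stated direction.

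The 2 replicates differed in a patterned way. Their difference at a tile correlated at 0.297 with that at the next tile, and at 0.290 without plate 1 of the TA series. Plate-wide shifts are not the whole cause, since 0.251 remained after plate medians were taken off, nor is a scale that differs at low or high ratios, since 0.282 remained after the means of 20 bins were taken off. A chromatin difference between the 2 seedling preparations may contribute. Nothing in the table separates it from the immunoprecipitation and amplification of each, or from the separate arrays to which each was hybridised. The clearest case is a run of 17 tiles in plate 1 of the TA series in which replicate 2 was lower by more than 0.538 log units (2 SD of the difference) at each tile, with medians of −0.096 in replicate 1 and −1.05 in replicate 2; the longest such run in 1000 shuffles within plates had 7 tiles.

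Tiles without a value were clustered, with 13 of the 54 in plate 56 of the TA series and 6 each in plate 86 of TA and plates 61, 66 and 81 of TB.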
